A study of Drosophila melanogaster with 4 samples.

How the data were processed

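Poly-A selected RNA from pooled heads of adult Drosophila melanogaster at day 30 was sequenced as paired ends, per the labels' protocols, in 4 samples. The 2 lamin-B overexpression samples carried an Hsp70-Gal4 driver and a UAS transgene for GFP-tagged lamin B. The 2 control sibling samples carried the UAS transgene without the driver. No sample carried the driver without the transgene. Siblings with and without a driver inherit different homologues of the chromosome that carries it. Effects of the driver, of variants linked to it and of the overexpression therefore cannot be told apart. The labels do not say whether the replicates of a group came from separate cultures. The p-values of single genes therefore measure only the spread between these samples, which may be technical. Those of gene lists and chromosome arms compare genes with other genes and measure no spread between samples.

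Reads were processed with STAR 2.5, HTSeq, DESeq2 1.22.1 and DESeq on build BDGP6, per the submitters' processing notes, which give these names without roles or order. Strand settings, annotation release and filters are not given in the sources used here. The analysis started from a table of the authors' own comparison with 1 row for each of 17753 genes. In it, the authors' deposited mean signal is the mean normalized count of a gene over the libraries of their fit. The authors' deposited log2 fold change comes with its standard error, and their deposited Wald score is the fold change divided by that error. The authors' deposited p-value comes with an adjusted p-value, which equals a Benjamini-Hochberg adjustment over the 11757 genes that have one, to within 1.86e-06. Genes with no reads numbered 2471, and 3525 genes had a p-value without an adjusted p-value, all with a mean normalized count of at most 7.96. The direction, overexpression over control, was read from the order of the group names the table carries, and Lam, the overexpressed gene, was positive.

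The design fixed before the data were examined assumed counts per library and a quasi-likelihood test on them. The tables used here hold none, so the test of each gene is the authors' own Wald test, and a gene was called at an adjusted p-value under 0.05. Normalization, filters applied before a fit and count models could therefore not be varied. The standard errors had an upper bound, as produced by shrinkage of the fold changes towards 0. The size of the change of genes with few reads is therefore understated. Shrinkage was undone with the bound's constant, 9.73, for the 4564 genes with a mean normalized count of at least 1000 and a standard error of at most 0.12. The same relation, checked on 618 genes of low mean whose reads were known, differed from the ratio of reads by a median of 0.01 on the log2 scale.

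Whole reads per library were recovered from the mean normalized count, which is a sum of 4 whole numbers each divided by its library's size factor and is printed to 10 significant digits. Recovery was limited to means of at most 100. A single solution was found for 5230 of 5230 genes with means up to 30, for 822 of 823 genes up to 60 and for 493 of 552 genes up to 100. Of random values in those ranges, 0.224%, 4.74% and 29.8% had a solution, so single solutions are least certain in the highest range. In data simulated with those size factors, 100%, 100% and 98.5% of genes had a single solution and 0 were wrong. There the true reads are a solution nearly by construction, so this checks the procedure and not the recovered reads. In the highest range the deposited data had fewer single solutions, 89.3%. The size factors were 1.10 and 1.15 for the overexpression libraries and 0.73 and 1.09 for the control libraries. A library's side was taken from the sign the authors' table gives to genes with 1 read in all, never from a gene's level, and the recovered libraries carry no replicate number. If the libraries were alike in composition, the size factors would put about 37.0 M and 38.4 M reads (M, 1000000 reads) in the overexpression libraries and 24.5 M and 36.5 M in the controls. Exact 95% binomial intervals are given for ratios of recovered reads, and a group at 0 was set to a floor of 3 reads over the group. Intervals and floors cover counting error only.

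Gene lists, 35 in number, were fixed before the data were examined. They were tested with the pre-ranked competitive test cameraPR in limma 3.58.1 (R 4.3.3) on the authors' Wald score, two-sided, with an inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. An estimated correlation and the test fry need values per library and were not run. On simulated scores of 11757 genes, lists of 40 members shifted by 1.5, 1, 0.75 and 0.5 Wald units were called in 87.2%, 36.7%, 15.3% and 2.67% of cases. Unshifted lists were called in 0.208%, so smaller shifts of a list could be missed. The simulated scores were independent between genes, so 0.208% is no estimate of false calls for lists whose members vary together. Median Wald scores were also placed among 10000 random lists matched on mean normalized count. Another 5 lists of organ transcripts were added after the data were examined. Calls on each of 6 chromosome arms were compared with the other arms by Fisher's exact test, two-sided. In 100 simulations on 11757 genes, random calls, drawn independently for each gene, gave an arm past the threshold in 6. Chromosome 4 was called in 94 when 25% of its genes were called.

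Symbols came from an identifier table that matched 17625 genes (99.3%), and positions from the Ensembl release 115 annotation of BDGP6.54, which belongs to the assembly series named in the submitters' processing notes. Of the called genes, 10 had no symbol and are not described. Genes are named by a rule fixed before the data were examined. It takes Lam, LamC, the Hsp70 paralogs and w. It adds, of called genes with a mean CPM of at least 5 (mean normalized counts scaled to a sum of 1000000), the 12 with the largest increase and the 12 with the largest decrease. It also takes up to 4 members of each list, by smallest p-value among called members or otherwise by highest mean. The rule's further condition, that both libraries of a group lie on the same side of the controls, could be applied only where reads were recovered. Reads per library were recovered for no gene with a mean CPM of at least 5. The 12 largest increases and the 12 largest decreases were therefore not screened by this condition. Alternatives were 2 other thresholds and a minimum expression for the arm test, planned beforehand, and others chosen after seeing the data. A second table with no named contrast was used for no comparison of the groups, and only its overlap with the lamin-B comparison is given. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.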

Results

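Gene expression was compared between heads of day 30 flies that overexpressed lamin B, the B-type lamin of the nuclear lamina encoded by Lam, and heads of control siblings that carried the transgene without its driver. Each group had 2 samples of pooled heads. The design asks which transcripts differ between overexpressing and sibling heads at this age. Fold changes, standard errors (SE) and adjusted p-values of single genes are those of the authors' deposited table, with changes shrunken towards 0, unless a ratio of recovered reads is named. Mean normalized counts summed to 33.5 M (M, 1000000) over all genes.

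Lam transcripts were higher in the overexpression heads, while LamC, which encodes the A-type lamin, did not pass the test. The largest increase was that of the ejaculatory bulb protein gene Ebp. Testis and accessory gland genes were higher as a list, with 16 of 28 called higher, and digestive enzyme genes had 17 of 45 higher and 1 lower. For these male tract and gut genes, carry-over of abdominal tissue cannot be told apart from a change within the heads. Phototransduction transcripts fell as a list, and the eye pigment list was lower with members in both directions. The authors' deposited comparison called 1027 of 11757 genes, 666 higher and 361 lower. Of these, 25 rose and 24 fell by at least 1 on the log2 scale of the shrunken fold change.

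Lam (FBgn0002525, chromosome 2L, 5542480 to 5546642) had a log2 fold change of 1.04 (SE 0.0801, adjusted p = 6.76e-36) in the authors' deposited table, and of 1.11 (SE 0.0858) with shrinkage undone. LamC (FBgn0010397, chromosome 2R, 14570810 to 14575771) stood at 0.14 (SE 0.0835, adjusted p = 0.391) in the authors' deposited table. Of 14 tested genes of the nuclear lamina and envelope, Lam alone was called, and the list did not pass the camera test (adjusted p = 0.272). Reads from the transgene's copy of Lam and from the native gene cannot be separated here.

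The driver carries an Hsp70 promoter, and many fly transgenes are marked with w, the white gene of eye colour. In the authors' deposited table w was higher, at 0.65 (SE 0.142, adjusted p = 2.28e-04). Hsp70Bb rose by 0.50 (SE 0.159, adjusted p = 0.0238) in the authors' deposited table. The other Hsp70 paralogs were low and none was called. Hsp70Ab had 47 and 59 recovered reads in the overexpression libraries and 15 and 59 in the controls. Hsp70Bc had 87 and 113 against 36 and 85, Hsp70Bbb 8 and 16 against 0 and 16, Hsp70Aa 10 and 5 against 11 and 11, and Hsp70Ba 2 and 0 against 0 and 1. These near-identical copies share reads, so the split among them is uncertain. Among 15 heat shock protein genes Hsp83 was also higher, at 0.15 (adjusted p = 0.0073) in the authors' deposited table, and the list was not called (camera adjusted p = 0.228).

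The largest increases belonged to genes of the male reproductive tract and to several others. Ebp (FBgn0004181, chromosome 2R, 25175126 to 25176715), which encodes a protein of the ejaculatory bulb, rose by 4.69 (SE 0.148, adjusted p = 4.81e-218) in the authors' deposited table. EbpII, from a neighbouring gene, rose by 2.50. The authors' deposited table gave 3.78 for the receptor gene mthl8, 2.56 for CG9029 and 2.35 for Bace. The seminal fluid protein genes Sfp87B, Sfp60F and Acp36DE rose by 2.23, 1.72 and 1.39 in the authors' deposited table. Jhbp5, CG17097 and the fatty acid synthase gene FASN2 rose by 1.78, 1.67 and 1.45 in the same deposited table. Arc1, a neuronal gene for a capsid-like Gag protein, was abundant (mean normalized count 17160.1) and rose by 1.72 (SE 0.0941, adjusted p = 1.5e-71) in the authors' deposited table.

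The largest decrease among genes with a mean CPM of at least 5 was that of CAH5. This carbonic anhydrase gene (FBgn0040629, chromosome 3R, 31262598 to 31263878) fell by 3.89 (SE 0.137, adjusted p = 4.98e-175) in the authors' deposited table. The authors' deposited table put CG7829, CG8329, CG32523, CG3088 and CG9676 lower by -3.23, -3.16, -2.93, -2.51 and -2.48. CG11211 stood at -3.03 in the authors' deposited table, and with shrinkage undone it and its neighbour CG8343 stood at -3.33 and -3.21. The neighbours Cpr72Ec and CG4842 stood at -2.40 and -1.95 in the authors' deposited table. The pigment gene se fell by 2.46 in the authors' deposited table. The same deposited table gave -1.80 for pkm, whose span overlaps that of nod, looked up after the values were seen and at -0.73. CG8329 had a mean normalized count of 39735, which makes its change the best supported by depth of these.

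**Figure D1:**
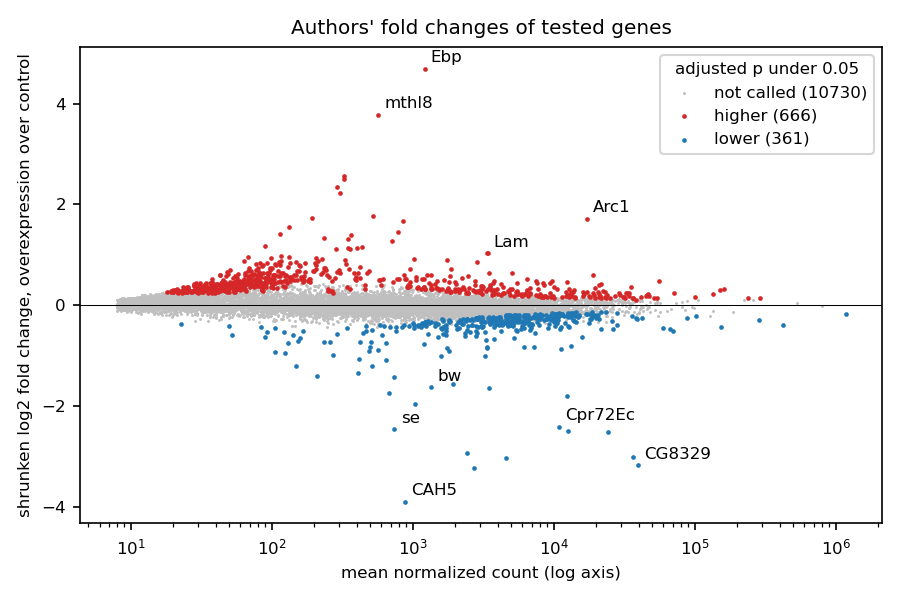
Shrunken log2 fold change of overexpression over control against mean normalized count (log axis) for the 11757 tested genes of the authors' deposited table, with 666 genes called higher in red and 361 called lower in blue. At means of 100 or less 314 genes were called higher and 6 lower.

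Calls depended on expression level. At a mean normalized count of 500 or more, 235 genes were called higher and 331 lower (41.5% higher), against 64.8% higher over all called genes of the authors' deposited table. Of the 272 genes called higher for which reads were recovered, 216 had at most 10 reads in the controls together and 64 had none. Among all 3020 tested genes with recovered reads, 48.5% had both overexpression libraries above both controls and 11.4% had both below, where chance gives 16.7% for each. These genes share the same 4 libraries, so this is a single split of libraries and not 3020 independent cases.

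**Figure D2:**
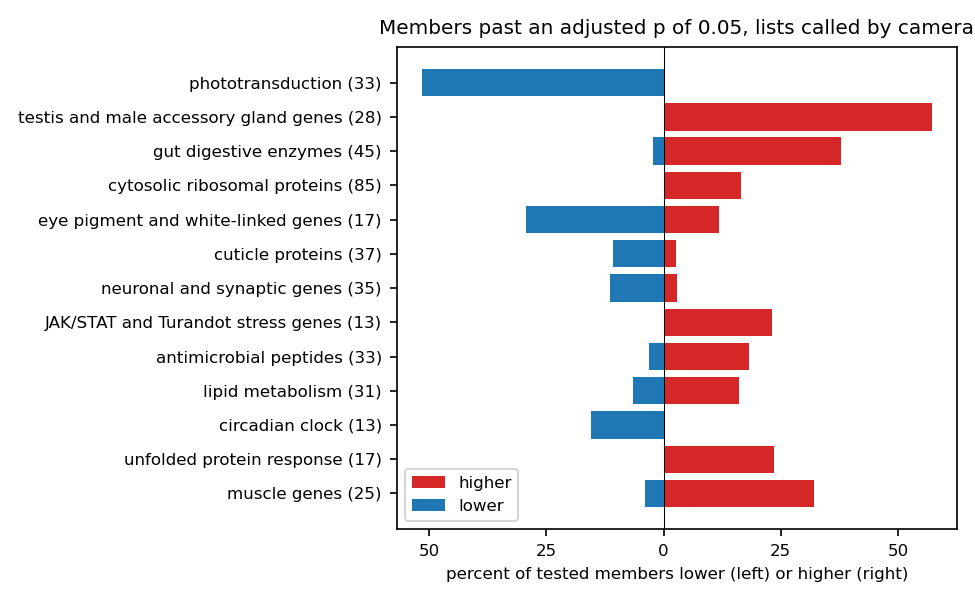
Percent of tested members called higher (right, red) or lower (left, blue) in the 13 gene lists past an adjusted p of 0.05 by camera, with the number of tested members in parentheses. Phototransduction had 17 of 33 members lower and none higher.

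Phototransduction genes were lower as a list. Of 33 phototransduction genes 17 were called lower and 0 higher in the authors' deposited table, and 19 lower and 1 higher adjusted over the list alone (camera adjusted p = 5.72e-23). Pdh, a retinoid dehydrogenase gene, fell by 0.81 (SE 0.0536), and retinin, of the corneal lens, fell by 0.62 (SE 0.063), in the authors' deposited table. The rhodopsin genes Rh4 and Rh6 fell by 0.48 (SE 0.0414) and by 0.46 (SE 0.0465) in the authors' deposited table. Eye pigment genes were split, with 5 of 17 lower and 2 higher, and 6 and 2 adjusted over the list alone (camera adjusted p = 4.70e-05, down). The median Wald score of the eye pigment list lay at percentile 8.80 of random lists matched on mean, within the middle 95%. Brown (bw, FBgn0000241, chromosome 2R, 23527805 to 23538499), a pigment transporter gene, fell by 1.63 (SE 0.105) and v, which encodes an enzyme of brown pigment synthesis, rose by 0.38 (SE 0.082) in the authors' deposited table.

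Neuronal and synaptic genes were lower as a list, with 4 of 35 called lower and 1 higher, and 5 and 1 adjusted over the list alone (camera adjusted p = 9.96e-04). The complexin gene cpx fell by 0.44, the neuronal RNA-binding gene elav fell by 0.34 and Snap25 fell by 0.28 in the authors' deposited table. The exception was ple, which encodes the tyrosine hydroxylase of dopamine synthesis, at 1.04 (SE 0.0738, adjusted p = 4.66e-42) in the authors' deposited table. Circadian clock genes had 2 of 13 lower, and 4 adjusted over the list alone (camera adjusted p = 0.0314, and 0.117 with a correlation of 0.05). Those were Pdf, the clock neuropeptide gene, and Pdp1, which fell by 0.38 and by 0.41 in the authors' deposited table. Glial markers had 1 of 20 higher, Gli at 0.28, and 1 lower, axo at -0.23, in the authors' deposited table (camera adjusted p = 0.514).

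Testis and male accessory gland genes were higher as a list, with 16 of 28 called higher and 0 lower, and 22 higher adjusted over the list alone (camera adjusted p = 2.48e-14). Reads were recovered for 18 of the 28, and 16 of these had at most 10 reads in the controls together. Acp26Aa, a seminal fluid peptide gene, had 217 and 129 recovered reads in the overexpression libraries with size factors 1.10 and 1.15 and 0 in both controls, at least 93.2-fold higher against a floor of 3 reads over the group. That bound became 55.8 and 37.4 without the control libraries with size factors 0.73 and 1.09 in turn. ProtB, a sperm chromatin gene, had 121 and 49 reads against 0 and 0. Mst84Dc, a testis transcript, had 215 and 45 reads against 8 and 4, a ratio of 17.5 (95% exact interval 9.86 to 34.3). Its ratio became 5.96 and 29.5 without the overexpression libraries with size factors 1.10 and 1.15 in turn, and 31.5 and 10.5 without the controls with 0.73 and 1.09. Acp32CD and Acp53C14b rose by 1.42 and 0.95 in the authors' deposited table. The authors' deposited table called 17 of 45 digestive enzyme genes of the gut higher and 1 lower, and 27 and 1 adjusted over the list alone (camera adjusted p = 4.46e-11). Mal-A7, Jon65Aiii and LysD rose by 1.34, 0.80 and 0.79 in the authors' deposited table. Over 19 gut genes with at most 10 control reads, the overexpression library with size factor 1.10 held 1612 reads and the other 491, a median ratio of 3.73 after normalization. The gut list did not pass among genes with a mean of 500 or more (adjusted p = 0.601), and its 6 members with shrinkage undone had a median of -0.05 against a test direction of up.

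**Figure D3:**
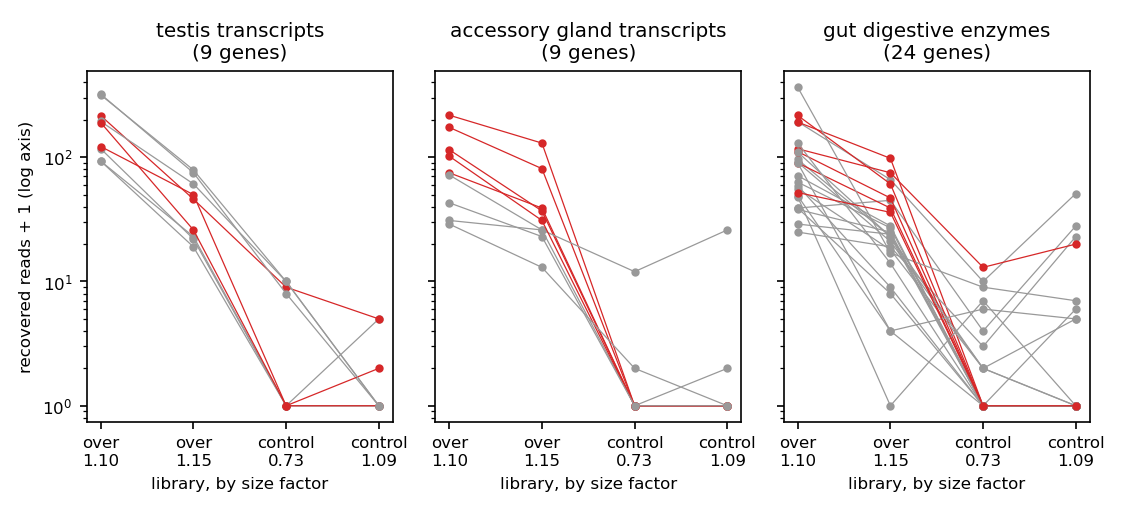
Recovered reads plus 1 (log axis) in each of the 4 libraries, shown by group and size factor, for 9 testis, 9 accessory gland and 24 gut transcripts with a mean normalized count of at most 100. Lines join values of 1 gene, red marks genes called higher, and both overexpression libraries hold more reads than either control for 38 of the 42 genes.

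No gene of the 9 for yolk and eggshell, which are made by females, was called (camera adjusted p = 0.512). Yp3 stood at -0.21 (adjusted p = 0.129) in the authors' deposited table. The dosage compensation RNAs roX1 and roX2, made by males, fell by 0.26 (SE 0.0464, adjusted p = 1.74e-06) and by 0.44 (SE 0.111, adjusted p = 0.00236) in the authors' deposited table. Of the 6 tested male dosage and male-biased head genes these were the 2 called, and the list was not (camera adjusted p = 0.0812).

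Of the immune and stress lists, those of antimicrobial peptides, JAK/STAT and Turandot genes and the unfolded protein response were called, and those of Toll and Imd, heat shock and oxidative stress defence genes were not. Antimicrobial peptide genes had 6 of 33 higher and 1 lower, and 8 and 1 adjusted over the list alone (camera adjusted p = 0.0112, and 0.117 with a correlation of 0.05). Drsl5, BomBc1 and BomS2 rose by 0.41, 0.36 and 0.27, while Def, the defensin gene, fell by 1.33, in the authors' deposited table. Toll and Imd pathway genes had 4 of 31 higher and the list was not called (camera adjusted p = 0.0812); the recognition gene PGRP-SA rose by 0.92 (SE 0.118, adjusted p = 8.18e-13), and nec, PGRP-SD and Rel rose by 0.32, 0.29 and 0.24, in the authors' deposited table. JAK/STAT and Turandot genes had 3 of 13 higher, and 3 adjusted over the list alone (camera adjusted p = 0.00562). These were TotX, TotM and vir-1, which rose by 0.65, 0.63 and 0.22 in the authors' deposited table. Genes of the unfolded protein response had 4 of 17 higher, and 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.039, and 0.139 with a correlation of 0.05). They were CaBP1, Gp93, Hsc70-3 and ERp60, chaperones and folding enzymes of the endoplasmic reticulum, at 0.27, 0.19, 0.18 and 0.15 in the authors' deposited table.

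Ribosomal protein genes were slightly higher as a list, with 14 of 85 called higher and 0 lower, and 28 higher adjusted over the list alone (camera adjusted p = 4.14e-08). RpS27, RpL4, RpL13 and RpL19 stood at 0.22, 0.19, 0.18 and 0.17 in the authors' deposited table. Lipid metabolism genes had 5 of 31 higher and 2 lower, and 6 and 2 adjusted over the list alone (camera adjusted p = 0.0218, and 0.139 with a correlation of 0.05). After FASN2 came Lsd-1, a lipid droplet gene, and the synthesis genes FASN1 and Desat1, which rose by 0.43, 0.31 and 0.23 in the authors' deposited table. Muscle genes had 8 of 25 higher and 1 lower, and 10 and 1 adjusted over the list alone (camera adjusted p = 0.0414, and 0.172 with a correlation of 0.05). Prm, Mlp84B, Act57B and Mhc rose by 0.44, 0.33, 0.29 and 0.17 in the authors' deposited table. Cuticle protein genes had 4 of 37 lower and 1 higher, and 4 and 1 adjusted over the list alone (camera adjusted p = 7.14e-04, and 0.234 on ranks). After Cpr72Ec these were led by Cpr49Ag and Cpr62Bb at -0.75 and -0.72, and Cpr100A was the member higher, at 1.16, in the authors' deposited table. Fat body markers went both ways, with 6 of 15 higher and 3 lower (camera adjusted p = 0.315), among them fon at 0.47 and the storage protein genes Lsp1beta and Lsp2 at -0.84 each in the authors' deposited table.

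Chromosome 4, the small fly chromosome rich in heterochromatin, had a larger share of its genes called than the other arms, nearly all lower. Of its 96 tested genes 26 were called, 25 of them lower, and 83 had a log2 fold change below 0 in the authors' deposited table. Lower calls made up 26.0% of its genes against 2.87% on the other arms (Fisher's exact test, two-sided, adjusted p = 3.87e-16 over 6 arms). The median log2 fold change was -0.19, and -0.22 over the 62 genes with shrinkage undone. The smallest p-values, looked up after the values were seen, belonged to pho, a Polycomb group gene, dati, CaMKII and Pur-alpha, at -0.45, -0.34, -0.41 and -0.49 in the authors' deposited table. The gene called higher was apolpp, a lipoprotein gene, at 0.14. The X chromosome had a smaller share called than the other arms (6.19% against 9.21%, exact adjusted p = 3.95e-05) and 2L a larger share (10.2% against 8.4%, exact adjusted p = 0.0197), which on 2L was lost among genes with a mean CPM of at least 5 (exact adjusted p = 0.957). On X, higher calls made up 3.66% against 6.04% (exact adjusted p = 1.41e-04) and lower calls 2.53% against 3.16% (exact adjusted p = 0.325). On 2L, higher calls made up 7.29% against 5.29% (exact adjusted p = 0.00131) and lower calls 2.88% against 3.11% (exact adjusted p = 0.754). Genes on an arm are not independent of each other.

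**Figure D4:**
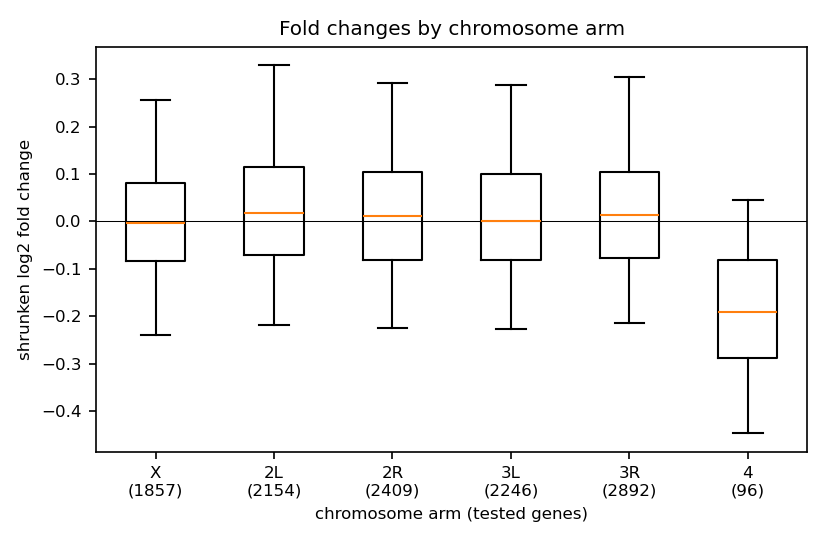
Shrunken log2 fold changes of tested genes by chromosome arm, with boxes from the first to the last quartile, a line at the median and whiskers from percentile 5 to percentile 95. Chromosome 4 (96 genes) has a median of -0.19, and the other arms have medians close to 0.

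Other lists fixed before the data were examined were not called by camera. Nuclear-encoded oxidative phosphorylation had 0 of 82 members called (adjusted p = 0.92), the mitochondrially encoded genes 0 of 15 (adjusted p = 0.228), the proteasome 0 of 31 (adjusted p = 0.0812), autophagy 0 of 23 (adjusted p = 0.949), oxidative stress defence 0 of 12 (adjusted p = 0.736) and DNA repair 0 of 24 (adjusted p = 0.92). Small RNA and transposon silencing genes had 0 of 24 (adjusted p = 0.797) and histone genes 0 of 5 (adjusted p = 0.66). The heterochromatin and Polycomb list had 2 of 28 lower, pho and esc, the latter at -0.54 in the authors' deposited table (camera adjusted p = 0.209). Insulin, TOR and FOXO genes had 2 of 25 higher and 2 lower (camera adjusted p = 0.438), with ImpL2, an insulin antagonist gene, at 0.55 and Ilp2, an insulin-like peptide gene, at -0.28 in the authors' deposited table. The authors' deposited table called 3 of 19 apoptosis and p53 or JNK targets higher, Ets21C at 0.57, Mmp1 at 0.31 and Diap1 at 0.16 (camera adjusted p = 0.686). Cytochrome P450 genes had 3 of 75 higher and 3 lower (camera adjusted p = 0.92), and glutathione S-transferases had 2 of 34 higher and 1 lower, GstE14 at -1.21 in the authors' deposited table (camera adjusted p = 0.92). Hemocyte markers had 2 of 18 lower and 0 higher, and 2 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.92, up). The lower ones were lz at -0.89 and PPO1 at -0.53 in the authors' deposited table, and the list's median was 0.07. Odorant-binding protein genes had 1 of 31 higher, Obp51a at 0.64 in the authors' deposited table (camera adjusted p = 0.949). Cytochrome P450, glutathione S-transferase, DNA repair and small RNA lists had a median fold change above 0 and a test direction of down.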

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

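The match of chromosome 4 genes on exonic length and expression level had its bounds set before its result was known. The other tests in this part were chosen after the results were seen. The bounds for testis release, nervous tissue and eye colour were set again after first values had been seen, and the missing-copy test was first left out and then taken back. Tests of carried-over female tissue, of dilution for chromosome 4 and of testis release for the gut transcripts were run and are not used. A second table of the authors' own comparison, with no named contrast and fitted on 6 libraries, was outside every comparison above and held 686 genes past an adjusted p of 0.05, 390 higher and 296 lower. Its log2 fold change for Lam was 0.20 (SE 0.193, adjusted p = 0.782). Across 14988 genes, which are not independent replicates, its fold changes had a Pearson r of 0.126 and a Spearman rho of 0.05 with those of the lamin-B comparison. Both tables called 118 genes, 104 with the same sign, where independent lists would share 52.8. Whether the tables share libraries is not known here, and shared libraries alone would raise this overlap.

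Many low-count transcripts of the male reproductive tract, gut and Malpighian tubule were near absent from the controls, while some abundant members of the same lists were not called higher in the authors' deposited table, among them EbpIII at 0.05 (mean normalized count 73769), Amy-p at -0.19 (11239.9) and Gld at -0.38. In EbpIII and Amy-p, at such means, a few added reads would not show, so these genes decide nothing about carry-over. More males among the overexpression heads is argued against by the male RNAs roX1 at -0.26 and roX2 at -0.44 in the authors' deposited table. The female yolk and eggshell list, not called, also leaned lower, with its median Wald score at percentile 1.155 of random lists matched on mean. That goes the other way, so the share of males is not settled. Carry-over of male abdominal tissue cannot be told apart from a change within the heads. All 5 lists for testis, accessory gland, ejaculatory tract, gut and tubule lay in the top 2.5% of random lists matched on mean. The gut list was part of the pattern itself, and the other 4 were written as separate lists after the rising genes were seen. Of these 4, the testis and accessory gland lists had 13 and 15 tested members, 5 and 11 called higher. Together they match in number the fixed list of 28, 16 called higher, which was also part of the pattern. Release of the testis transcripts by lamin-B overexpression was not settled. Their median ratio of 4.42 between the overexpression libraries, over 8 genes, cannot be set beside that of Lam, whose reads per library are not known. The standard error of Lam with shrinkage undone, 0.0858 on the log2 scale, is small beside such a split. It comes from the fit over both groups, and is not the split of Lam between the 2 overexpression libraries. LamC, which was not called, had a like error, 0.0902. A release of these 8 genes in proportion to Lam therefore stays open, as do other forms of release. The 5 lists hold 14 of the 216 genes called higher with at most 10 control reads, and no source was tested for the others.

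Chromosome 4 transcripts were lower as a group. Of 10000 random lists matched on mean and exonic length 0 had a median Wald score as low. That argues against exonic length or expression level as the cause, and length with introns was not matched. A missing copy in all overexpression flies without compensation is argued against by the median fold of 0.857 with shrinkage undone (95% bootstrap interval 0.836 to 0.891), which leaves a compensated or partial loss open. A lower share of nervous tissue cannot be told apart from an effect of the chromosome: the chromosome 4 median lay 0.0302 above that of the neuronal and synaptic list (95% bootstrap interval -0.04 to 0.09), and with shrinkage undone the direction turned, at -0.22 over 62 genes against -0.15 over 16 members (difference -0.07, interval -0.17 to 0.07). GC content stays open and was not tested. The overexpression, the driver and variants linked to it also stay open and cannot be told apart here.

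Phototransduction transcripts were lower as a list. Dilution of head RNA by carried-over tissue as the whole cause is argued against by the glial markers alone. Phototransduction genes lay at -0.14 from them in median log2 fold change with shrinkage undone (95% bootstrap interval -0.31 to -0.05). The neuronal and synaptic list fell too, with an undone median of -0.15 over 16 members beside -0.19 over 32, and a shrunken median of -0.22 beside -0.18. That difference was not tested, so a fall particular to the eye is not shown. The 32 members did not fall equally: they ranged from -1.17 to 0.11, a spread beyond their standard errors (Cochran's Q = 507 on 31 degrees of freedom). This cannot decide on an equal loss of all eye tissue, since members also expressed outside the eye would fall less. The eye colour of the flies cannot be told apart from the groups, because w differed with the driver (0.65). The overexpression itself stays open and was not tested apart from the driver.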

How the results depend on the processing

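All alternatives here other than the thresholds of 0.1 and 0.01 and the minimum expression for the arm test were chosen after seeing the data. No paired analysis was possible because the table used gives 1 fold change per gene and the recovered libraries carry no replicate numbers. Not run, since they need counts per library: other normalizations, the planned count filters, other count tools and robust fits, a minimum fold test, refits without a replicate or without the 20 most abundant genes, an estimated correlation, fry, and a comparison of a refit with the authors' table. At a threshold of 0.01 the 1027 calls became 592, 388 higher and 204 lower, fewer by construction. Among genes with a mean of 500 or more, adjusted anew, 573 were called, 237 of them higher, since fewer genes were tested, and the share higher was 41.4%. Lists called went from 13 to 8 with a correlation of 0.05 and to 8 with fold changes in place of the Wald score; the cause was not tested for the latter. Of the 13 lists, 5 were called under all 4 alternatives: phototransduction, ribosomal proteins, eye pigment, JAK/STAT and Turandot, and neuronal genes, with adjusted p-values of at most 1.32e-07, 0.043, 0.0437, 0.0369 and 0.0433. Testis and accessory gland genes were called under the 3 that could be run (at most 7.37e-08), having too few members with a mean of 500 or more. The other 7 lost the call in at least 1. Another 4 lists, Toll and Imd, proteasome, mitochondrially encoded genes and heterochromatin, were called under at least 1. Set among random lists matched on mean, 12 of the 13 called lists had a median Wald score in the outer 2.5% on the side of their test, eye pigment being the exception, as had 6 of the 22 not called: Toll and Imd, proteasome, fat body, hemocyte, yolk and eggshell, and mitochondrially encoded genes. Lam stayed at 1.04 to 1.11. Fold changes of genes with few reads are shrunken towards 0, so depth limits what can be said of their size.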

Other observations

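The organ lists in this part were written after the values were seen and are given as counts with no test, apart from the gut list and the list of ovary and maternal transcripts, which were written before their values were known. The testis and accessory gland lists, of 13 and 15 tested members, match in number the fixed list of 28, so for these only the separation may be later. The split of organ transcripts between the overexpression libraries is given as values, and no difference between organs was tested. Genes in the sums of reads had at least 20 recovered reads in all and at most 10 in the controls, so the low control totals follow from that choice. Testis transcripts had 9 of 13 higher adjusted over the list alone (5 over all genes), and 8 of the 13 with at most 10 control reads each held 1440 reads in the library with size factor 1.10 and 347 in the other, against 25 and 5 in the controls. The ratio of these genes between the overexpression libraries ranged from 2.56 to 7.84. Accessory gland transcripts had 11 of 15 called higher, with 779 and 372 reads over 8 genes against 1 and 1 in the controls and ratios from 1.24 to 3.49. Gut enzymes gave 1612 and 491 reads over 19 genes against 14 and 13, with ratios from 1.26 to 30.8. Ejaculatory duct and bulb transcripts had 3 of 6 higher and 1 lower, Dup99B among the former at 1.17 and Gld the latter at -0.38 in the authors' deposited table. Over the 216 low genes called higher, the ratio between the overexpression libraries had a median of 2.85 (0.815 to 7.84).

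Malpighian tubule transcripts went both ways, with 4 of 11 higher and 2 lower. Uro, the urate oxidase gene of the tubule, had 187 and 64 recovered reads against 0 and 0 in the controls. Oatp58Db had 67 and 57 against 0 and 2. Drip, an aquaporin gene, rose by 0.85 and Oatp58Dc fell by 0.44 in the authors' deposited table. Ovary germline and maternal transcripts had 1 of 6 higher, exu at 0.69 in the authors' deposited table (camera adjusted p = 0.152), and exu is also used in the male germline.

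Some called genes lie close together. On 3L, Cpr72Ec (16365894 to 16367340) and CG4842 (16368389 to 16369518) adjoin and were lower, at -2.40 and -1.95 in the authors' deposited table. Pdh (16353233 to 16354297) and retinin (16331933 to 16332789), lower at -0.81 and -0.62 in the authors' deposited table, lie on the same stretch with other genes between. On X, roX2 (11579065 to 11580432) and pkm (11581957 to 11584175) were lower, at -0.44 and -1.80 in the authors' deposited table. The span of pkm lies within that of nod, looked up after the values were seen and lower at -0.73 in the authors' deposited table, and the strand setting of the counts is not given in the sources used here. On 2R, CG8343 and CG11211 adjoin and were both lower. No test of neighbourhood was run.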
